A study of Salmo salar with 120 samples.

How the data were processed

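Gene counts from 120 RNA-seq libraries of Atlantic salmon head kidney and spleen were used as deposited. Per the labels' protocols, RNA was extracted with QIAzol from 10 fish per diet and site, all samples had RNA integrity values of at least 7, and libraries were sequenced on a NovaSeq instrument as 150 bp read pairs to a stated depth of 30 M reads (M, 1e6). Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 and counted with featureCounts 1.4.6-p1. Per the file headers, the deposited counts came from featureCounts v1.5.1 with strand setting 2 and read pairs counted, on the Ssal_v3.1 annotation, so the notes and the headers name different versions. The kit's strandedness is not given in the sources used here. Per the file headers, 3 head kidney fjord D1 libraries (replicates 51, 53 and 54) were counted from another user's directory. No option for reads that align in several places appears in the headers; salmon carries many duplicated genes, so values of near-identical copies are uncertain.

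Each file held 61216 features, of which 16391 had a gene symbol and 44825 only a locus number; the symbol features took a median of 33% of the counts. Of the features, 54002 matched the reference gene table by identifier and 53908 of these had the same start and end. Descriptions were not used, so lists were matched by symbol and cover only symbol features. Total counts per library ran from 5.94 M to 28.33 M.

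Tissues were analysed apart. In each, the 6 groups of site and diet entered 1 fit with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM scaling, filterByExpr by group), run in R 4.3.3. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05. The sites were compared with diets weighted equally, and diet by site by a joint test of both interaction terms. CPM values use the TMM-scaled library sizes and are given as mean ± SD over fish; log2 changes are given ± SE.

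Before the data were examined, 30 gene lists for immune, stress and metabolic pathways, blood cell types and neighbouring tissues were fixed, along with the groups, tests, other settings to try and the rule for naming genes. The rule took, per comparison, the 10 largest changes each way among genes past the threshold with a symbol, a mean of at least 1 CPM in the higher group and at least 80% of fish of each group beyond the other group's median, plus up to 4 called members of each list with the smallest p. Exceptions chosen after their values were seen are LOC106584588, the values of hs90a outside coast D2 and the genes given for single libraries. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 420 list tests, camera called 107, of which 7 held with the estimated correlation (heat shock in both tissues for D2 against D1 and D3 against D2 at the coast, glucocorticoid response in coast spleen for D2 and D3 against D1, and cholesterol synthesis in coast spleen for D3 against D2); fry, which tests whether a list moves on balance one way, called 56. A list score per fish is the median over members of log2(CPM + 0.5) less its tissue mean.

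Sample identity was examined with 199 genes that were on in some fish (above 3 CPM) and off in others (below 0.3 CPM). Pairs within a tissue that correlated above 0.9 over these genes were taken as 1 fish and their counts summed. This step was chosen after the values were seen, and its alternative counts each library separately. Head kidney and spleen libraries whose sample numbers differ by 30 matched best in 46 of 60 cases, against at most 16 in 9999 random pairings within groups; in the fjord D1 group, where repeats leave 5 spleen fish, 2 of 10 matched. The tissue score, over 1228 genes, and the median correlation with the own group served to find libraries that stood apart: 2 head kidney libraries with a spleen profile and 1 spleen library with a median correlation of 0.746, where all other spleen libraries reached at least 0.920. These 3 stayed in the main results, and an added alternative leaves them out.

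Other settings fixed in advance were median-ratio size factors, no expression filter, DESeq2 1.42.0, fits of the compared libraries alone and, at the coast, the number run of the libraries as a term. Added after seeing the data were separate libraries, fits without the 3 outlying libraries, the nephron score as a term and leaving out each of the 5 spleen fjord D1 fish. In head kidney, fits of the fjord groups alone, the same with a term for the lower or higher 5 sample numbers of each group, and fits without fjord D3 replicate 45 were added as well. The term for sample number was not fitted in spleen, where all D1 fish are of lower number. List tests under these settings, list tests of coast spleen D3 with the number run, and diet regroupings without the 3 outlying libraries and replicate 45 were added too, as were thinning of all libraries to the smallest total, spleen regroupings without fjord D1 replicate 85, head kidney list tests without fjord D1 replicates 57 to 60, fits of the coast libraries alone with and without the number run, with diets regrouped within runs, and the dose order in fish that did not serve to call the genes. This last test took the place of an earlier one on genes called from all fish (median log2 change of 0.11 for D3 against 0.52 for D2), and its prediction was rewritten after that value was seen. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

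The steps were tested on simulated counts with the real means, spreads and library sizes. For head kidney fjord D2 against D1 (31312 genes), edgeR found 64% of 100 genes changed 2-fold and 88% of 100 changed 4-fold, with 9 false among 161 calls; for spleen (31446 genes) it found 72% and 91%, with 13 false among 176. Where nothing had been changed it called 0 genes in each tissue. DESeq2 found 71% and 91% in head kidney with 29 false of 191, and 79% and 94% in spleen with 31 false of 204. A planted list was found and 0 of 50 unchanged lists were called in each tissue. The simulated genes varied independently of each other, and no outlying library was simulated. These checks therefore do not show how often false calls arise in the real libraries, where random regroupings of the fish gave up to 5972 genes.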

Results

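Messenger RNA was sequenced from the head kidney and the spleen of farmed Atlantic salmon (Salmo salar). The head kidney is the main blood-forming organ of bony fish, and the spleen filters blood and holds lymphocytes and red cells. Fish were fed 1 of 3 diets at 2 sea farms, a coastal site and a fjord site. Diet 1 (D1, the control) contained 5% sunflower meal, diet 2 (D2) 5% fermented sunflower meal and diet 3 (D3) 10% fermented sunflower meal. The deposited set held 120 libraries, 10 for each of the 12 combinations of tissue, site and diet. Total gene counts ran from 5.94 M to 28.33 M per library (M, 1e6 counts), with a median of 12.83 M. Median totals were higher at the fjord site (16.18 M in head kidney, 15.62 M in spleen) than at the coast (11.56 M and 11.92 M).

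Some libraries appeared to share a fish. In spleen from the fjord D1 group, the 10 libraries formed 5 pairs whose on or off pattern over 199 variably expressed genes correlated at 0.925 to 0.979, and the counts within a pair differed by only 1.59 to 1.86 times the sampling noise. The median for other pairs of that group was 14.82 times. In head kidney, 1 pair of the fjord D1 group, replicates 52 and 54, had the same kind of pattern (r = 0.959), although its counts differed by 4.29 times the noise, which is not below the lowest value of other head kidney pairs (3.20), so this pair rests on the pattern alone. No other pair of the 3540 compared exceeded 0.772. Counts were summed within each of these pairs, which left 5 fish in spleen fjord D1 and 9 in head kidney fjord D1. In the other groups n = 10.

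The first question was how fermented meal at the same inclusion as the control changed expression at the coast. In coast head kidney, genes of protein folding rose together in D2 fish. The cytosolic chaperone hs90a (chromosome 15, 52296584 to 52307382 in Ssal_v3.1) rose from 8.01 ± 2.48 CPM (counts per 1e6 counts) in D1 to 246 ± 65.2 CPM in D2 (SD, n = 10 fish each), a log2 change of 4.94 ± 0.45 (SE, adjusted p = 2.3e-11). The J-domain co-chaperone dnaja rose by 2.30 ± 0.27, and the endoplasmic reticulum stress genes manf, dnajc3a and canx rose by 1.90 ± 0.18, 1.38 ± 0.18 and 0.67 ± 0.09. For each of these 5 genes all 10 D2 fish lay above the D1 median and all 10 D1 fish below the D2 median. In the heat shock and unfolded protein list, 14 of 24 members rose, also 14 when adjusted over the list alone (camera adjusted p = 2.2e-10, adjusted p = 0.0019 with an estimated correlation).

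Several genes of myeloid cells and of the acute phase also rose in coast D2 head kidney, although their lists did not pass. Of the macrophage and neutrophil list 3 of 16 members rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.063), and of the acute phase list 2 of 8 rose by either adjustment (camera adjusted p = 0.46). The collagenase mmp13 went from 1500 ± 630 to 8810 ± 2740 CPM (log2 2.55 ± 0.38) and the gelatinase mmp9 from 1590 ± 533 to 6170 ± 1380 CPM (1.95 ± 0.33). The transcription factor cebpb rose by 1.00 ± 0.19. The iron regulator hamp (3.32 ± 0.79), the acute phase gene saa5 (2.90 ± 0.86) and acod1, which makes itaconate in activated macrophages (3.35 ± 1.00), rose from low levels. The neutrophil peroxidase mpx fell by 0.95 ± 0.34 (adjusted p = 0.05 as rounded; 0.065 with no expression filter). The iron exporter slc40a1 fell by 1.12 ± 0.27. The myosin binding protein mybpc2a and the RNA-editing family member adarb2 fell by 3.98 ± 0.67 and 2.74 ± 0.40, from 2.82 and 2.75 CPM in D1.

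Further lists moved in the same tissue with less firm tests. Proteasome subunits rose in 8 of 13 members (10 adjusted over the list alone; camera adjusted p = 8.8e-06, adjusted p = 0.38 with an estimated correlation), psmd8 by 0.52 ± 0.09. Cholesterol synthesis rose in 4 of 16 (5 adjusted over the list alone; camera adjusted p = 0.0061, adjusted p = 0.38 with an estimated correlation), among them hmgcs1 (0.83 ± 0.13) and idi1 (0.73 ± 0.13). The first enzyme of fatty acid synthesis, acaca, rose by 1.23 ± 0.14. Glucocorticoid-response genes rose in 6 of 13 members by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.38 with an estimated correlation), with klf9 at 1.20 ± 0.26, cebpd at 1.05 ± 0.20 and tsc22d3 at 0.71 ± 0.17. Immediate early genes rose in 6 of 20 (8 adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.78 with an estimated correlation), jun by 1.27 ± 0.35 and atf3 by 0.95 ± 0.26. Markers of other cells moved too: the erythroid score went from 0.57 ± 0.27 in D1 to 0.03 ± 0.30 in D2 (SD), with 1 of 13 members higher by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.035 downward, adjusted p = 0.80 with an estimated correlation), and the adipose score from -0.04 ± 0.52 to 0.46 ± 0.40, with 2 of 5 members higher, also 2 adjusted over the list alone (camera adjusted p = 0.25). Changes within cells are therefore not separated from changes in the mix of cells. The mitotic genes prc1b and ccnb2 fell by 0.73 ± 0.16 and 0.75 ± 0.19.

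By edgeR's quasi-likelihood test, 4064 of 31783 genes changed in coast head kidney between D2 and D1, 2941 higher and 1123 lower. Size factors from median ratios gave 2415 higher and 1490 lower, and the compared libraries alone 3303 and 2547. The coast libraries alone gave 3223 and 3131, and 3227 and 3166 with the number run of the libraries as a term, so the balance of directions depends on the scaling and on the libraries fitted. Genes of the kidney tubule, a tissue that adjoins the blood-forming part, were high in some fish of every coast group: the nephron score was above 2 in 5 of 10 D1, 6 of 10 D2 and 3 of 10 D3 fish, with no fish between -0.76 and 2.91.

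**Figure D1:**
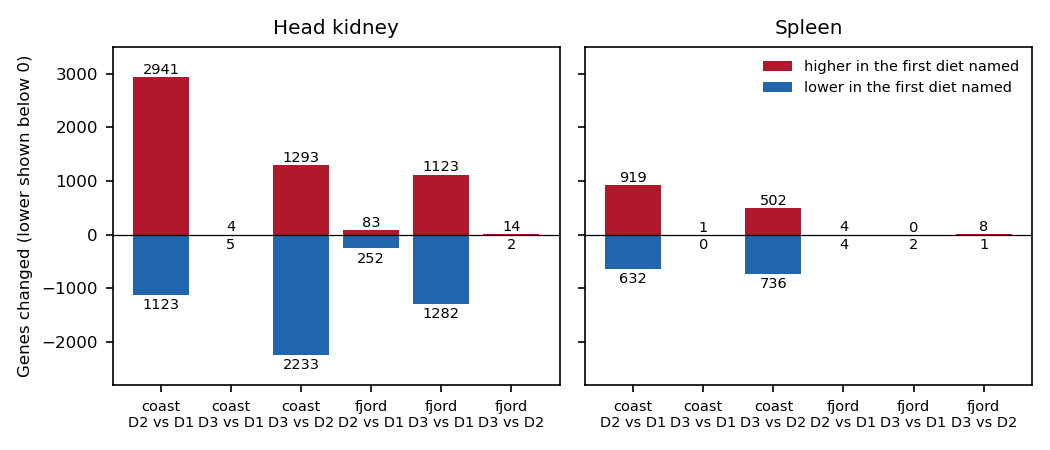
Genes changed in each diet comparison by edgeR's quasi-likelihood test, in head kidney and spleen. Bars above 0 count genes higher in the first diet named and bars below 0 genes lower, with the number at each bar; coast D2 against D1 reached 4064 genes in head kidney and 1551 in spleen.

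In coast spleen, several myeloid genes were higher in D2 fish. The gelatinase mmp9 rose to 1570 ± 386 CPM in D2 (log2 3.24 ± 0.50, adjusted p = 0.00011, n = 10 fish each, all 10 beyond the other group's median on both sides). Also higher were mmp13 (2.99 ± 0.51), the inflammatory receptor gpr84 (3.31 ± 0.74), the lipoxygenase family member loxe3 (2.58 ± 0.50), antithrombin (2.60 ± 0.57), cebpb (1.39 ± 0.26) and the granulocyte growth factor receptor csf3r (1.16 ± 0.25). The macrophage and neutrophil list rose in 5 of 17 members by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 6.5e-07, adjusted p = 0.22 with an estimated correlation). B cell genes fell in 3 of 6 members, also 3 adjusted over the list alone (camera adjusted p = 0.00021, adjusted p = 0.40 with an estimated correlation), with pou2af1, a coactivator of immunoglobulin genes, at -1.36 ± 0.32 and the adaptor blnk at -0.81 ± 0.23. The tetraspanin cd37 of mature lymphocytes fell from 99.3 ± 29.4 to 23.2 ± 4.59 CPM (-2.10 ± 0.39). The T cell score also went from 0.4 ± 0.14 in D1 to 0.13 ± 0.16 in D2 (SD). Changes within cells are not separated from changes in the mix of cells here either.

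Stress genes of coast D2 spleen moved in the direction seen in head kidney. The glucocorticoid-response list rose in 7 of 13 members, also 7 adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.033 with an estimated correlation), with dusp1 at 1.32 ± 0.26 and klf9 at 1.43 ± 0.31. The heat shock list rose in 4 of 25 (7 adjusted over the list alone; camera adjusted p = 5e-06, adjusted p = 0.033 with an estimated correlation), with manf at 1.21 ± 0.20 and dnajc3a at 1.10 ± 0.22. The iron exporter slc40a1 fell by 0.98 ± 0.25. Cell cycle genes fell in 3 of 32 (6 adjusted over the list alone; camera adjusted p = 6.5e-07, adjusted p = 0.42 with an estimated correlation), mcm6 by 0.61 ± 0.13. In all, 1551 of 31741 genes changed, 919 higher and 632 lower. The number rose to 4179 with only the compared libraries fitted, to 4617 with the coast libraries alone, 4710 with the number run as a term added and to 2968 without the outlying libraries described with the fjord groups. Of 506 genes called in both tissues, 490 had the same direction. The log2 changes correlated across 29739 genes at r = 0.39, where genes are not independent replicates. By their on or off pattern over variably expressed genes, the head kidney and spleen libraries of coast D1 and D2 came from the same fish. Agreement between the tissues is therefore not independent replication.

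**Figure D2:**
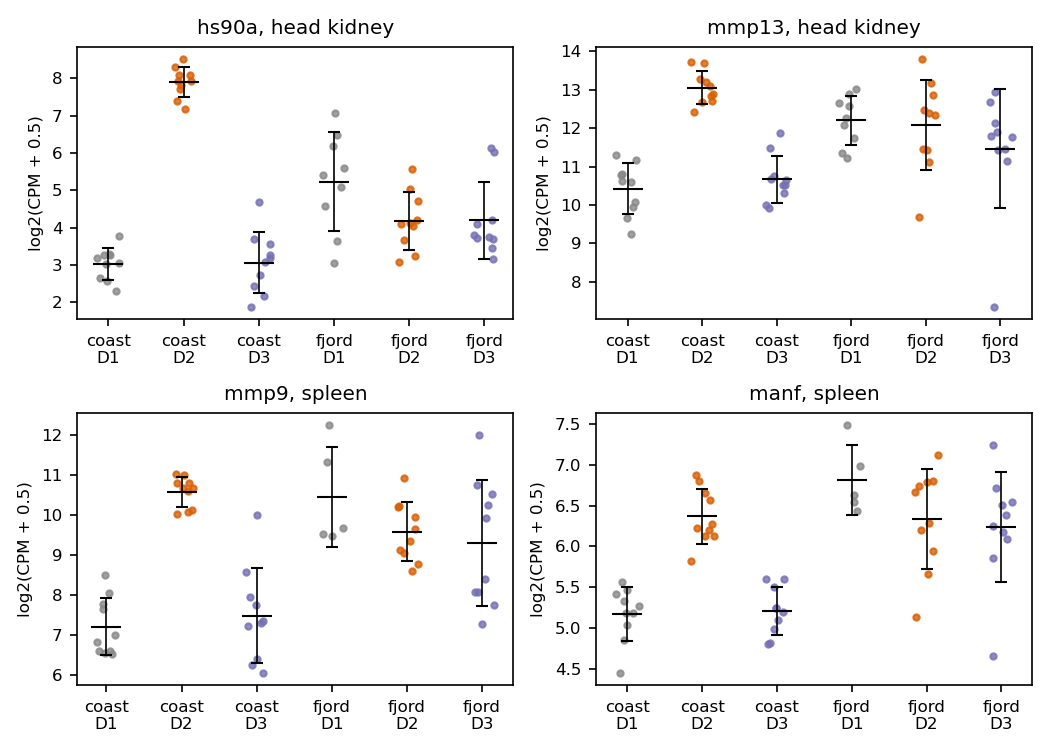
Expression of hs90a and mmp13 in head kidney and of mmp9 and manf in spleen, as log2(CPM + 0.5) on the vertical axis, for each fish by site and diet. Bars give the mean and SD of each group; in head kidney the median of hs90a was 243 CPM in coast D2 and 8.14 CPM in coast D1.

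The next comparison set D3 against D1 at the coast. These diets differ in both the inclusion and the fermentation of the meal, so the comparison does not separate the 2. In coast head kidney, D3 raised tsc22d3, a glucocorticoid-induced leucine zipper gene, from 65.3 ± 13.2 CPM in D1 (log2 0.87 ± 0.17, adjusted p = 0.036, n = 10 fish each). The immunophilin fkbp2 rose by 0.35 ± 0.07 and relch fell by 0.37 ± 0.08. With no expression filter these 3 genes no longer passed (adjusted p = 0.063, 0.11 and 0.081). The heat shock gene hs90a was at 9.27 ± 6.44 CPM in D3. Only 9 genes changed, 4 higher and 5 lower, with 2431 at an unadjusted p under 0.05. DESeq2 gave 31, the fit of the compared libraries alone 52, the coast libraries alone 99 and with the number run 94, and the fits with no expression filter or with the nephron score 1. In coast spleen 1 gene, LOC106584588, rose by 1.78 ± 0.30 (adjusted p = 0.0064), and DESeq2 gave 23. The glucocorticoid-response list stood higher in D3 spleen (camera adjusted p = 8.1e-09, adjusted p = 0.0089 with an estimated correlation), with 8 of 13 members higher adjusted over the list alone. Its score was uneven within D3, at 0.14 to 0.46 in the 5 fish of lower sample number and -0.37 to -0.07 in the other 5, against -0.78 to -0.25 in D1. With the number run as a term on coast libraries, 6 of 12 members were higher adjusted over the list alone (camera adjusted p = 3.7e-12, adjusted p = 0.0028 with an estimated correlation). That term shifts all diets alike, so it does not address a rise confined to part of the D3 fish. Spleen genes of exocrine pancreas, which lies beside the spleen in salmon, gave a score above 2 in 4 of 10 D3, 2 of 10 D2 and 1 of 10 D1 coast fish.

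D3 and D2 were then set against each other at the coast, where the same D2 fish served. Heat shock genes were lower in D3 in 11 of 24 members in head kidney (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.7e-08, adjusted p = 0.013 with an estimated correlation) and in 4 of 25 in spleen (6 adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.014 with an estimated correlation). Cholesterol synthesis genes were lower in 5 of 16 in head kidney (9 adjusted over the list alone; camera adjusted p = 0.00033, adjusted p = 0.16 with an estimated correlation) and in 2 of 16 in spleen (7 adjusted over the list alone; camera adjusted p = 3.8e-05, adjusted p = 0.014 with an estimated correlation). In head kidney 3526 genes differed (1293 higher, 2233 lower in D3), and in spleen 1238 (502 higher, 736 lower). The spleen count was 2788 without the outlying libraries, 3665 with only the compared libraries and 4351 with the number run on coast libraries. The head kidney split was 1674 higher and 1887 lower with median-ratio size factors, 1478 and 1468 with no expression filter, and 2916 and 2789 with the number run on coast libraries, so its direction is not firm.

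At the fjord, immediate early genes stood higher in head kidney under both fermented diets. The matricellular gene cef10 rose from 1.65 ± 0.74 CPM in D1 (SD, n = 9 fish) to 20.0 ± 15.0 in D2 and 17.2 ± 15.7 in D3 (n = 10 each), log2 changes of 3.56 ± 0.65 and 3.35 ± 0.65. The growth arrest gene btg2 rose by 1.55 ± 0.29 and 1.85 ± 0.29, ier2 by 1.60 ± 0.33 and 1.75 ± 0.33, and junb by 1.57 ± 0.33 and 1.72 ± 0.33. Of 20 list members, 8 rose in each comparison (10 higher in each adjusted over the list alone, with 1 lower in D3; camera adjusted p = 2.1e-09 for D2 and 2.2e-05 for D3, adjusted p = 0.094 and adjusted p = 0.48 with an estimated correlation). The list score followed sample number: it was 0.37 to 0.72 in D2 replicates 36 to 40 and 0.31 to 0.83 in D3 replicates 46 to 50, but -0.35 to 0.01 and -0.39 to 0.25 in the other 5 fish of each group, and -0.61 to 0.13 in D1. A fit of the fjord groups alone called 0 members in D2 and 7 in D3 (9 in each adjusted over the list alone), with median log2 changes of 0.62 and 0.43. Adding a term for the lower or higher 5 sample numbers to that fit left 0 and 7 (9 and 8 adjusted over the list alone; camera adjusted p = 6.4e-11 and 8.7e-06, adjusted p = 0.021 and adjusted p = 0.33 with an estimated correlation), with medians of 0.53 and 0.39. This term shifts all groups alike, so it does not address a rise confined to part of a group. The T cell coreceptor cd8a rose by 1.39 ± 0.28 in D2 and 1.13 ± 0.27 in D3.

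Antiviral genes were higher in 4 of the 9 D1 fish of fjord head kidney, which set the differences of both fermented diets from D1. The interferon regulator irf7 was at 11.9 ± 8.49 CPM in D1, 4.22 ± 2.53 in D2 (log2 -1.49 ± 0.40) and 3.95 ± 2.46 in D3 (-1.58 ± 0.40). The D2 change of irf7 stood close to the threshold (adjusted p = 0.046; 0.051 with median-ratio size factors and 0.066 with no expression filter). Of 17 members of the type I interferon list, 1 fell in D2 and 2 in D3 (15 and 14 adjusted over the list alone; camera adjusted p = 3e-10 and 1.3e-06, adjusted p = 0.36 and adjusted p = 0.50 with an estimated correlation). The 4 fish were D1 replicates 57 to 60, with list scores of 1.35 to 2.25 (mean 1.74), against a mean of 0.04 in the other 5 D1 fish, -0.04 in D2 and -0.07 in D3. Without them 0 members passed in either comparison, also 0 adjusted over the list alone (camera adjusted p = 0.90 for D2 and 0.87 for D3), with median log2 changes of 0.02 and 0.20. In the fjord groups alone, 13 members in D2 and 1 in D3 were lower adjusted over the list alone, and 0 and 1 with the term for sample number, although the median log2 change was about as large (-1.08 and -0.90 without the term, -0.82 and -0.87 with it; camera adjusted p = 4.4e-09 and 8.7e-06 with it, adjusted p = 0.59 and adjusted p = 0.61 with an estimated correlation). The matrix proteoglycan vcanb fell by 1.86 ± 0.37 and 1.95 ± 0.37, the chemokine ccl19a.1 in D3 by 1.22 ± 0.31 and saa5 in D3 by 3.27 ± 0.84. In D3, metallothionein mt2 rose by 1.34 ± 0.22 and ribosomal protein genes rose in 14 of 46 (37 adjusted over the list alone; camera adjusted p = 1.7e-12, adjusted p = 0.53 with an estimated correlation). The ribosomal shift rested largely on 1 fish, D3 replicate 45, with a score of 1.84 where the other D3 fish reached at most 0.42. Without it 1 member rose (0 adjusted over the list alone; camera adjusted p = 0.00043, adjusted p = 0.66 with an estimated correlation). The steroidogenic genes fdx1b and hsd3b1, markers of interrenal tissue within the head kidney, had D1 means of 42.3 and 78.8 CPM but D1 medians of 0.303 and 4.31, so a few fish carried the difference.

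Counts for fjord head kidney depended strongly on which libraries set the spread. With all groups in one fit, 335 genes changed in D2 (83 higher, 252 lower) and 2405 in D3 (1123 higher, 1282 lower; 1243 and 1120 with median-ratio size factors, 1647 and 1547 with DESeq2). With only the compared libraries, edgeR called 0 genes for D2 (3559 at an unadjusted p under 0.05; DESeq2 on all groups gave 1071) and 74 for D3. Every gene named above for D2, cef10 included (adjusted p = 0.063), no longer passed in that fit. For D3, mt2, hsd3b1, vcanb, irf7, ccl19a.1 and saa5 no longer passed there (adjusted p = 0.053, 0.073, 0.076, 0.098, 0.11 and 0.11), whereas cef10, btg2, ier2, junb and cd8a did. Of these libraries 2, D2 replicate 40 and D3 replicate 42, carried a spleen profile: the egg-hatching enzyme family gene hce1 was at 16.3 and 34.3 CPM, against a head kidney median of 5591 and a spleen median of 20.1, and mpx was at 64.4 and 48.9 against 2405 and 68.1. Without the outlying libraries 580 genes changed in D2 and 2131 in D3.

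Few genes were called between D3 and D2 in fjord head kidney. Metallothionein mt2 was among 16 genes called (14 higher, 2 lower in D3), and ribosomal protein genes stood higher as a list (camera adjusted p = 8e-15, adjusted p = 0.79 with an estimated correlation), 16 of 46 members adjusted over the list alone. Without replicate 45 the ribosomal list no longer passed (camera adjusted p = 0.15), with 0 members adjusted over the list alone, whereas the count of genes went up to 1.1e2, 5 of them lower. DESeq2 called 309, and edgeR on the compared libraries alone 0, with 1484 at an unadjusted p under 0.05. With no expression filter 28 were called, 13 higher and 15 lower, so the balance of directions is not firm.

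Fjord spleen gave few calls for diet. The lysosomal protease gene ctsbb was lower in D2, at 1.00 ± 0.655 CPM (n = 10 fish) against 22.6 ± 47.2 CPM in D1 (n = 5 fish; log2 -4.48 ± 0.68, adjusted p = 0.00075 by edgeR; 0.54 with only the compared libraries). This call rests on 1 fish, D1 replicate 85, since the medians were 1.63 CPM in D1 and 0.688 in D2. Ribosomal protein genes stood higher in both fermented diets as a list (camera adjusted p = 1.9e-35 in D2 and 1e-24 in D3, adjusted p = 0.26 and adjusted p = 0.81 with an estimated correlation), 39 and 37 of 46 members adjusted over the list alone. T cell genes were higher in D2 in 7 of 13 members adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.66 with an estimated correlation). By edgeR 8 genes changed in D2, 2 in D3 and 9 between D3 and D2, where DESeq2 gave 62, 249 and 37. With each library counted as its own fish the D2 calls were 94 higher and 55 lower, and the D3 count was 2770. The erythroid regulator gata1 was at 894 CPM in D3 replicate 77, against a spleen median of 91.1, and the lymphocyte genes cd79b and cd37 at 2.42 and 1.01 against 94.1 and 90.8. Without this library edgeR called 65 genes in D2, 0 in D3 (3064 at an unadjusted p under 0.05) and 3 between D3 and D2.

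The diet effects were compared between sites by the interaction of diet and site. In head kidney 1681 genes passed and in spleen 735 (228 without fjord D1 replicate 85), and hs90a was among them (adjusted p = 2.7e-10 in head kidney). Across genes, coast and fjord log2 changes had Pearson correlations of 0.01 for D2 and 0.32 for D3 in head kidney and of -0.08 and 0.19 in spleen. Random regroupings of the fish gave -0.55 to 0.61, -0.71 to 0.69, -0.31 to 0.32 and -0.42 to 0.28, so none of the 4 values lay outside chance. Spearman correlations were 0.06, 0.28, -0.14 and -0.17, so the sign for D3 in spleen depends on the measure. The D2 lists of head kidney shared 43 genes between sites, against 42.8 for independent lists (Fisher's exact test, one-sided p = 0.51).

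D2 and D3 effects within a site share the D1 fish. In fjord head kidney 284 genes were called in both, all in the same direction, against 25.3 for independent lists. The covariance of the log2 changes was 0.292, against 0.124 in simulated unchanged groups, but it was -0.368 when the D1 fish were split so that each diet had its own, and single splits ran from -0.678 to 0.074. Observed, simulated and split covariances were 0.062, 0.115 and 0.005 in coast head kidney, 0.082, 0.052 and 0.052 in coast spleen, and 0.193, 0.100 and 0.075 in fjord spleen.

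The sites were compared with the 3 diets weighted equally. In head kidney, plasma protein genes made mainly by liver stood higher in fjord fish: hp was at 6.40 ± 9.0 CPM (n = 29 fish) against 0.0494 ± 0.114 (n = 30), log2 7.09 ± 0.76, hpxb rose by 7.52 ± 0.82 and fgg by 5.51 ± 0.64. The liver score was above 2 in 10 of the 29 fjord fish and in 0 of the 30 coast fish. Nephron genes were lower in 11 of 13 members (12 adjusted over the list alone; camera adjusted p = 0.17), with slc12a1 at -6.01 ± 1.05, slc12a3 at -5.87 ± 1.05 and cubn at -3.51 ± 0.54 (SE). With the nephron score, which is made of such genes, as a term, slc12a1 and slc12a3 no longer passed (log2 -0.38 and -0.23). The nephron score was above 2 in 2 of the 29 fjord fish and 14 of the 30 coast fish. T cell genes were lower in 10 of 13 and higher in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.62 with an estimated correlation), among them gata3 (-1.36 ± 0.12), eomes (-1.32 ± 0.13) and tbx21 (-0.97 ± 0.11), which control T and natural killer cell fates.

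**Figure D3:**
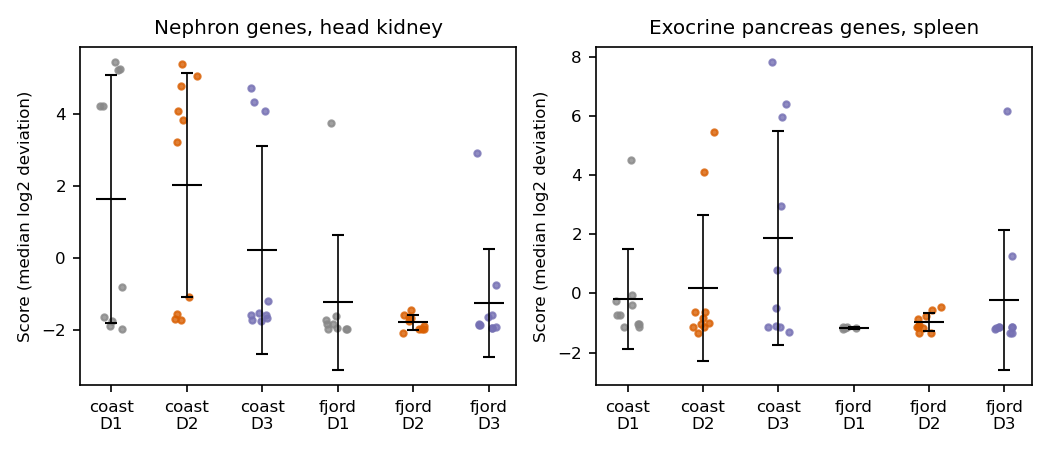
Score of nephron genes in head kidney and of exocrine pancreas genes in spleen for each fish by site and diet, as the median log2 deviation of the list's genes from their tissue mean. Bars give the mean and SD; nephron scores fell into a low cluster up to -0.76 and a high cluster from 2.91.

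Machinery of protein turnover and translation stood higher in fjord head kidney. All 13 proteasome members rose by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 4.4e-11, adjusted p = 0.21 with an estimated correlation), psma5 by 0.75 ± 0.05. Ribosomal protein genes rose in 44 of 46, also 44 adjusted over the list alone (camera adjusted p = 8.3e-13, adjusted p = 0.68 with an estimated correlation), rps12 by 0.57 ± 0.05. Cell cycle genes rose in 19 of 32 and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.68 with an estimated correlation), ccnb1 by 0.93 ± 0.10. Interferon genes rose in 13 of 17 by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.042, adjusted p = 0.72 with an estimated correlation), mx2 by 1.78 ± 0.35. Without fjord D1 replicates 57 to 60 the interferon list no longer passed (camera adjusted p = 0.26), with 6 of 17 members higher (4 adjusted over the list alone) and a median log2 difference of 0.36 in place of 0.70. Altogether 20910 genes differed, 9502 higher and 11408 lower in fjord fish. With the nephron score as a term the balance turned, with 9144 higher and 7760 lower. Each site is 1 farm, so site cannot be told apart from fish stock, sampling day or library preparation.

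Spleen differed between sites in many of the same genes. T cell genes were lower in fjord fish in 11 of 13, also 11 adjusted over the list alone (camera adjusted p = 0.00033, adjusted p = 0.68 with an estimated correlation), tbx21 at 52.1 ± 22.2 CPM (n = 25 fish) against 99 ± 17.1 (n = 30; log2 -1.03 ± 0.14). The cytokine il17a/f3 fell by 3.46 ± 0.51 and the clock gene per3 by 1.03 ± 0.17. Proteasome genes rose in 12 of 13, also 12 adjusted over the list alone (camera adjusted p = 8.7e-09, adjusted p = 0.28 with an estimated correlation), and oxidative phosphorylation genes in 30 of 34 (31 adjusted over the list alone; camera adjusted p = 2.8e-09, adjusted p = 0.63 with an estimated correlation). Macrophage and neutrophil genes rose in 13 of 17 (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.81 with an estimated correlation), and hamp by 3.91 ± 0.59. B cell genes rose in 4 of 6 and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.46), blnk and pou2af1 by 1.07 ± 0.14 and 1.12 ± 0.19 and blk by -0.72 ± 0.14. In all 15725 genes differed, 8704 higher and 7021 lower. Of 11497 genes called in both tissues, 10987 had the same direction. Many of the head kidney and spleen libraries matched as the same fish, so this agreement is not independent replication either.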

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

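The tests of the nephron score, of dose order, of stress scores per fish and of doubled fjord fish were chosen only after the results were seen. So were the regroupings of head kidney and those with libraries left out or within number runs. Predictions for coast doubling, too few fish, spleen thinning and the main spleen regroupings were written beforehand. Coast doubling and too few fish were nevertheless conceived after the repeat libraries were seen. The screen for fish or libraries standing apart had no written prediction.

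The strongest diet pattern was the difference of coast D2 fish from coast D1 fish in both tissues, with 4064 genes in head kidney and 1551 in spleen. Chance among single fish is argued against, since 1 of 60 regroupings, the real one, gave as many genes in each tissue (highest other 596 and 1). The regroupings moved single fish. They do not address differences between units that several fish may have shared, such as runs of sample numbers. Nephron tissue is argued against as the whole cause, because 5016 genes passed with the nephron score as a term. A larger change with more fermented meal is also argued against: over head kidney genes called between 5 D2 and 5 D1 fish, the median log2 change in the same direction, measured against the other 5 D1 fish, was 0.10 for D3 and 0.67 for the other 5 D2 fish (medians over 20 draws), and below 50% of the D2 value in all 20. What stays open is handling or sampling of that group, which cannot be told apart from diet D2, since its 10 fish share 1 group. All 10 had a head kidney heat shock score above every coast D1 fish, as had 6 of 10 in spleen. These scores cannot decide between handling and diet, because they restate the heat shock list already called for the same fish.

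A second pattern was fjord spleen, where D3 against D1 gave 2 genes with repeat libraries summed and 2770 with each library taken as a fish. Too few fish for any call is argued against only for a contrast as large as coast D2. Coast D2 against 5 coast D1 spleens still gave a median of 239 genes (69 to 505 over draws), from 1551 with 10. Most calls were lost there, so this test does not exclude lost power at the fjord. In the main fit, fjord D3 against D1 had 5429 genes at an unadjusted p under 0.05. Doubling 5 coast D1 fish gave a median of 2.5 genes for D3 (highest 8), below the bound set beforehand, so doubling did not produce such counts among coast fish. Fjord fish behaved differently, which is why a further test was added: doubling 5 fjord D2 spleens gave a median of 29 genes for D3 against D2, up to 915, with 4 of 20 draws above 100. Its median lay below the bound of 100 written for it, which would have argued against doubling; the verdict was changed to open after that value was seen, because of the single draws. Doubled fjord fish may therefore account for part of the 2770 genes, and whether they account for all stays open.

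The third pattern was the site difference, 20910 genes in head kidney and 15725 in spleen. Chance among single fish is argued against, with 1 of 40 regroupings as large in each tissue (highest other 3968 and 23). These regroupings also moved single fish, so they do not address what the fish of a site shared. Nephron tissue is argued against as the whole cause in head kidney, with 16904 genes called with its score as a term, and deeper sequencing at the fjord site is argued against in spleen, with 13567 genes called after thinning every library to 5.94 M counts (M, 1e6). In head kidney the same thinning, added later, left 18263. Fish stock, sampling day and library batch remain open and were not tested, as does the site itself.

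The diet effect differed between sites in 1681 genes in head kidney and 735 in spleen by the interaction test. As many genes came up in 2 of 60 regroupings in head kidney (highest other 2338) and in 2 of 60 in spleen (highest other 1039). Such regroupings undo every diet effect, not only its difference between the sites. The low share therefore speaks only against no diet effect at either site, and does not test equal effects at both. Even for that, chance is not excluded, since a single regrouping exceeded the real count in each tissue. Without the 3 outlying libraries and head kidney fjord D3 replicate 45, 2548 and 1513 genes passed, and 1 of 60 regroupings, the real one, gave as many in each tissue. For spleen the low share depends on 1 fish. Without fjord D1 replicate 85 the count was 228, which 7 of 60 regroupings reached (highest other 3062), so the share is not low there and chance is not excluded.

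Of 60 combinations of group and measure examined for 1 fish or library standing apart, 11 had such a value. Chance gives about 3.0 for independent, normally spread values. Scores that fall into clusters, such as the nephron score, are not of that kind. Among total counts these were 7.83 M in spleen coast D1 and 15.6 M in spleen coast D2. Nephron scores of 3.73 in a head kidney fjord D1 fish and 2.91 in a fjord D3 fish stood above the rest of their groups, as did interferon scores of 1.39 in a coast D3 and 2.00 in a fjord D3 head kidney. Exocrine pancreas scores of 4.52 in a spleen coast D1 fish and 6.16 in a fjord D3 fish stood above the rest. The spleen heat shock score of -0.41 in fjord D3 belonged to replicate 77. Glucocorticoid-response scores of -0.78 in spleen coast D1 and 0.64 in spleen coast D2 completed these.

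The remaining diet counts were set against regroupings of the same fish, without adjusting the shares for the number of counts examined. These moved single fish among the diets of a site. Chance therefore means chance among single fish here, not among runs of sample numbers. For head kidney, D3 against D2 at the coast (3526 genes) was reached in 2 of 60 regroupings (highest other 5972). Chance is unlikely there but not excluded, since a regrouping gave more genes. D3 against D1 at the fjord (2405) was reached in 1 of 60 (highest other 917), which argues against chance among single fish in the fit of all groups. Scores there split by sample number, which moving single fish does not address. The count was 628 with the fjord groups alone and 74 with only the compared libraries, and no regroupings were run for those fits. Chance is not excluded for D3 against D1 at the coast (9 genes, 4 of 60, highest other 1332), for D2 against D1 at the fjord (335 genes, 5 of 60, highest other 947) or for D3 against D2 at the fjord (16 genes, 20 of 60, highest other 1506). All coast regroupings, in either tissue, mixed D2 fish into the groups compared. For D3 against D1 they therefore do not measure chance between D1 and D3 fish alone. In coast libraries alone with the number run as a term and diets regrouped within each run, D3 against D1 gave 94 genes in head kidney (reached in 2 of 60, highest other 3958) and 8 in spleen (1 of 60, highest other 1). The share for coast D3 against D1 thus depends on the libraries fitted and the term. For spleen, D3 against D2 at the coast (1238 genes) was reached in 1 of 60 (highest other 2). Chance is not excluded for D3 against D1 at the coast (1 gene, 4 of 60, highest other 38), nor at the fjord for D2 against D1 (8 genes, 24 of 60, highest other 4349), D3 against D1 (2 genes, 30 of 60, highest other 4813) and D3 against D2 (9 genes, 22 of 60, highest other 3152). Without replicate 77, the highest counts of other regroupings for these 3 spleen comparisons were 454, 29 and 850, with real counts of 65, 0 and 3. Without replicates 40, 42 and 45 in fjord head kidney, D2 against D1 (893 genes) was reached in 1 of 60 (highest other 823), D3 against D1 (2286) in 1 of 60 (highest other 243) and D3 against D2 (43) in 9 of 60 (highest other 1029), so whether chance is excluded for D2 at the fjord depends on which libraries are kept.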

How the results depend on the processing

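Separate libraries, fits without the outlying libraries, the nephron score, the fits of the fjord groups alone, the term for sample number there and the fish left out were chosen after seeing the data; the other alternatives were planned. Of the alternative values for counts and comparisons, 76 stayed near the reported value and 76 did not. Of 997 alternative values for the gene results, none changed sign, 874 stayed on their side of the threshold, 1 newly passed and the rest no longer passed. Of these, fits of the compared libraries alone held 56, all but 2 of them in fjord head kidney, and fits of the fjord head kidney groups alone, with and without the term for sample number, held 22 each. Thinning every library to 5.94 M counts (M, 1e6), the smallest total, also after seeing the data, lowered all counts: in head kidney to 3307, 3 and 2894 for coast D2 against D1, D3 against D1 and D3 against D2, to 218, 1857 and 6 for the same fjord comparisons, to 18263 for the sites and 1215 for diet by site, and in spleen to 1268, 0, 981, 7, 0, 0, 13586 and 584 in the same order (877, 4603 and 3138 at an unadjusted p under 0.05 for the counts of 0). A separate draw for the spleen sites gave 13567. Within a tissue the groups compared share no sample number, so fish could not be paired between diets or sites. Many head kidney and spleen libraries did match as the same fish, but the tissues were analysed apart and no analysis paired them.

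With median-ratio size factors, coast spleen D3 against D1 gave 2 genes. With no expression filter, head kidney gave 1 gene for coast D3 against D1, 210 for fjord D2 against D1, 28 for fjord D3 against D2 and 1041 for diet by site; spleen gave 37 for fjord D2 against D1 and 0 for fjord D3 against D2 (4888 at an unadjusted p under 0.05). DESeq2 gave 31 for coast D3 against D1, 1071 for fjord D2 against D1 and 309 for fjord D3 against D2 in head kidney, and in spleen 23 for coast D3 against D1, 62, 249 and 37 for the fjord comparisons D2 against D1, D3 against D1 and D3 against D2, and 1284 for diet by site.

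With only the compared libraries fitted, head kidney gave 52 for coast D3 against D1, 0 for fjord D2 against D1, 74 for fjord D3 against D1 and 0 for fjord D3 against D2 (3559 and 1484 at an unadjusted p under 0.05 for the counts of 0). Spleen gave 4179 for coast D2 against D1, 3665 for coast D3 against D2, and 0, 0 and 0 for the fjord comparisons (2154, 1321 and 844 at an unadjusted p under 0.05). The same fits without the outlying libraries gave 0, 92 and 0 in fjord head kidney (4503 and 2360 at an unadjusted p under 0.05 for the counts of 0) and 0, 0 and 0 in fjord spleen (2154, 1993 and 935). The spread is then estimated from fewer fish; the cause was not tested further. With the number run as a term, fitted on coast libraries alone, head kidney gave 6393, 94 and 5705 for D2 against D1, D3 against D1 and D3 against D2, and spleen 4710, 8 and 4351; the same libraries without the term, added after seeing the data, gave 6354, 99 and 5761, and 4617, 2 and 4362.

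With each library counted separately, head kidney gave 4 for coast D3 against D1 and 193 for fjord D2 against D1, and spleen 1.5e2 (94 higher and 55 lower) for fjord D2 against D1, 2770 for fjord D3 against D1 and 1667 for diet by site. Without the outlying libraries, head kidney gave 580 for fjord D2 against D1, and spleen 2968 for coast D2 against D1, 2 for coast D3 against D1, 2788 for coast D3 against D2, 65, 0 and 3 for the fjord comparisons (3064 at an unadjusted p under 0.05 for the count of 0) and 1513 for diet by site. With the nephron score as a term, head kidney gave 1 for coast D3 against D1, 644 for fjord D2 against D1 and 56 for fjord D3 against D2. The 3 fjord groups of head kidney alone gave 0, 628 and 0 for D2 against D1, D3 against D1 and D3 against D2 (2853 and 1847 at an unadjusted p under 0.05 for the counts of 0), and 0, 509 and 0 with a term for the lower or higher 5 sample numbers of each group (2578 and 1809). Leaving out fjord D3 replicate 45 gave 1.1e2 (5 of them lower) for D3 against D2. Leaving out 1 of the 5 spleen fjord D1 fish in turn gave 1 to 23 genes for D2 against D1, 0 to 18 for D3 against D1 (4209 at an unadjusted p under 0.05 without replicate 85, the fish that gave 0) and 228 to 1079 for diet by site, 228 being without replicate 85. The cause was not tested for these.

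Over the gene lists, camera with an estimated correlation called 7 and fry 56 of 420 tests. Splitting the D1 fish moved the covariance of D2 and D3 effects from 0.062 to 0.005 in coast head kidney, from 0.292 to -0.368 in fjord head kidney, from 0.082 to 0.052 in coast spleen and from 0.193 to 0.075 in fjord spleen, where the split itself removes the shared fish.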

Other observations

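The test of coast D2 fish against fjord levels was chosen only after the results were seen, as were the comparisons of libraries here.

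Clock genes were among those lower in fjord head kidney. They fell in 9 of 16 members and rose in 2 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.32), with per3 at 1.93 ± 0.965 CPM in fjord fish (n = 29) against 4.19 ± 0.967 at the coast (n = 30; log2 -1.12 ± 0.13). The time of sampling is not given in the sources used here. The gene th, for the rate-limiting enzyme of catecholamine synthesis and a marker of chromaffin cells, also fell by 2.62 ± 0.45.

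Coast D2 fish lay near fjord levels for some of the genes named for them and not for others. In head kidney manf was at 130 ± 16.6 CPM in coast D2, against 98 ± 42 CPM in fjord D1, the lowest of the fjord means, and 35 ± 6.65 in coast D1, and mmp9 was at 6170 ± 1380 against 6440 ± 2410, 5610 ± 3260 and 4440 ± 2220 in fjord D1, D2 and D3. In contrast, hs90a was at 246 ± 65.2 CPM in coast D2 and at 51.4 ± 41, 20.2 ± 12 and 23.9 ± 23 in the fjord groups. List scores were mixed too. The mean head kidney heat shock score was 0.18 in coast D2 and 0.10, 0.12 and 0.16 in fjord D1, D2 and D3. The head kidney glucocorticoid-response score was 0.34 in coast D2, -0.38 in coast D1 and -0.42, -0.15 and -0.17 in these fjord groups. The spleen B cell score was -0.60 in coast D2, 0.17 in coast D1 and 0.20, 0.31 and 0.09 at the fjord. These last 2 moved away from the fjord. A hypothesis is that coast D2 fish shared a state with the fjord fish, such as a response to handling, infection or feeding. With coast D3 as the reference for the fjord level, so that no fish entered both differences, 87.4% of the 4064 genes called in head kidney and 75.8% of the 1551 in spleen moved toward the fjord level. Of 100 regroupings of the coast D1 and D2 fish, the real one included, 1 in head kidney and 3 in spleen had as high a share among as many top genes (real 86.4% and 75.8%, highest other 84.5% and 78.5%), so such a state may exist, and these data do not name it. Over all genes the correlation was 0.26 in head kidney, which 42 of 100 regroupings reached, and 0.23 in spleen, which 3 reached.

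Fish identity across tissues was uneven. Head kidney libraries matched the spleen library numbered 30 higher first in 10 of 10 cases for coast D1, 10 of 10 for coast D2, 9 of 10 for coast D3, 8 of 10 for fjord D2 and 7 of 10 for fjord D3, and in 2 of 10 for fjord D1, where 5 of the 10 spleen libraries repeat others, so that part of the low share follows from the repeats.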
